A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

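Gene expression was measured with Affymetrix yeast arrays in 4 cultures of the haploid laboratory strain W1588-4c of Saccharomyces cerevisiae. Per the labels' protocols, cells grew in synthetic complete medium with 2% glucose at 30 °C to an optical density of about 1. They were then left untreated or given 0.4 mM allyl alcohol for 3 h, and biotin-labelled cRNA was made from 6 µg of total RNA. The sources used here give no such time for the untreated cultures. A difference in growth time, if there was any, could not be told apart from treatment. Each condition had 2 arrays, which the labels describe as independent experiments.

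The deposited values are RMA signals, one for each probe set and array, and RMA and Affymetrix Expression Console are named per the submitters' processing notes; their versions are not given in the sources used here. The deposited values were read as log2 because they lay between 2.78 and 14.75 on all arrays. RMA combines background correction, quantile normalization between arrays and a median polish over probes, which fits all arrays together, so a broad change in total mRNA is partly removed. The settings used are not given in the sources used here. Scanner files were not used here, so the arrays could not be normalized anew from their probes, and no scan dates or other batch records were used.

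The table held 10928 probe sets, of which 166 were controls. The platform annotation gave 1 gene for 7244 probe sets, several for 1 and none for 3683, of which 3517 were not controls. Names were updated through the RefSeq gene table of assembly R64 (GCF_000146045.2), which changed 12 symbols. Of the probe sets with 1 gene, 5498 matched an S. cerevisiae gene of that table. The other 1746 carried gene names from outside it, and the array also holds probe sets for another yeast species. The comparison used 5449 S. cerevisiae genes. For the 47 genes with several probe sets, the set with the highest mean over all 4 arrays stood for the gene.

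Background was set on each array as the 95th percentile of the 1746 probe sets with names outside the S. cerevisiae table. It was 5.58 and 5.28 on the arrays labelled untreated replicates 1 and 2, and 5.33 and 5.64 on those labelled allyl alcohol replicates 1 and 2. On these arrays 5340, 5418, 5409 and 5310 genes were above it, and 49 genes were not above the mean background in their mean over arrays. Where an array's signal lay below background, a difference is given as a bound computed from that array's background. The number of arrays limits the precision.

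Groups followed the sample labels throughout. Allyl alcohol was compared with untreated in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the deposited log2 values, no block, two-sided tests and Benjamini-Hochberg adjustment over all genes tested at 0.05. A gene was counted as at least 2-fold changed where it also had an absolute log2 difference of at least 1. A total of 37 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera was also run with an estimated correlation, and fry was run as a second test. The percentile of a list's median difference between arrays was taken among 10000 random lists of the same size, drawn from 10 bins of mean signal.

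The rule for named genes, set before the data were examined, took the 12 largest rises and the 12 largest falls past the threshold whose groups did not overlap, up to 4 members past the threshold of each list described, and ADH1, ADH2, OYE2, OYE3, GSH1, GSH2, YAP1, RPN4, MSN4 and GCN4 whatever their values. If fewer than 24 genes passed, the genes with the largest differences and non-overlapping groups were to be given as values without a call, and this was the case; the 12 largest were taken in each direction. Genes named for differences between arrays of the same label were chosen after their values were seen, as those with the largest such difference in a list or among all genes.

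The gene test was tested on simulated data with 200 changed genes among 5449, 50 at each size. With the measured spread between arrays of the same label it called 0, 0, 24 and 50% of genes with absolute log2 changes of 1, 2, 4 and 6, and no unchanged gene. With the spread seen within labels at the 1746 probe sets named outside the S. cerevisiae table, it called 66, 88, 94 and 100%, and 7 unchanged genes. Those probe sets also set the background, so they do not stand for expressed genes. Noise was drawn independently for each array. On the measured arrays, deviations of same-numbered arrays from their group means correlated at -0.973 across genes. The simulated percentages therefore need not hold for the measured arrays. The list test was tested with that second spread: it called both of 2 lists shifted by 0.5 in their direction and 0 of the other lists. Noise was drawn independently for each gene, so this does not cover false calls among lists whose genes move together. The measured arrays held such lists, with an estimated correlation of 0.90 for cytosolic ribosomal proteins. This estimate comes from the differences between arrays of the same label.

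The alternatives planned before the data were examined were the replicate number as a block, an intensity trend and a robust prior in eBayes, leaving out dim probe sets, testing all probe sets, quantile normalization of the genes anew, centring each array on its median, the mean of a gene's probe sets, the 5322 genes with a single unambiguous probe set, each array left out in turn, a test against the fold bound, and the other list tests. A block that pairs the arrays crosswise was added after seeing the data. Control probe sets, unnamed probe sets and the probe set with several genes stayed out of the gene comparison. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.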

Results

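Transcript levels were measured in yeast grown to an optical density of about 1. The cells were then left untreated or exposed to 0.4 mM allyl alcohol for 3 h, with 2 arrays in each group. Allyl alcohol is the unsaturated alcohol that yeast alcohol dehydrogenases oxidise to acrolein, a reactive aldehyde that binds thiols such as glutathione. The comparison asks which transcripts differ after this exposure. Between 97.4% and 99.4% of the 5449 genes tested were above background on an array. Over these genes the arrays of the same label correlated less than arrays of different labels did in the closest cases. Pearson's r across genes, which are not independent replicates, was 0.757 between the arrays labelled untreated and 0.740 between those labelled allyl alcohol. It was 0.996 between the array labelled untreated replicate 1 and that labelled allyl alcohol replicate 2, and 0.991 between untreated replicate 2 and allyl alcohol replicate 1. Samples are therefore named by their labels throughout, and every direction below is that of the labels.

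By these labels no gene passed the test. The genes for the enzymes that handle allyl alcohol and acrolein had similar group means. ADH1, the main fermentative alcohol dehydrogenase, had a log2 signal of 14.01 ± 0.28 (SD, n = 2) in untreated and 14.03 ± 0.10 (SD, n = 2) in allyl alcohol samples. ADH2, the glucose-repressed isoenzyme, had 10.03 ± 0.53 and 9.73 ± 0.29. GSH1, the first enzyme of glutathione synthesis, had 12.005 ± 1.52 and 11.93 ± 1.44, and GSH2, the second, had 12.04 ± 0.02 and 11.89 ± 0.02. The old yellow enzymes, NADPH oxidoreductases that reduce unsaturated carbonyls, had 13.96 ± 0.49 and 13.91 ± 0.45 for OYE2, and 11.55 ± 3.68 and 11.52 ± 3.62 for OYE3.

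The regulators fixed beforehand had a like pattern. YAP1, the transcription factor of the oxidative stress response, had 11.58 ± 1.00 in untreated and 11.61 ± 1.27 in allyl alcohol samples (SD, n = 2), a log2 difference of 0.03 with a standard error of 0.90. RPN4, the activator of proteasome genes, had 12.61 ± 2.05 and 12.62 ± 2.03, and GCN4, the activator of amino acid synthesis, had 13.38 ± 0.53 and 13.39 ± 0.53. MSN4, a general stress factor, had 10.79 ± 0.70 and 10.45 ± 0.65. The adjusted p in limma was 1 for each of these 10 genes. The large SDs came from pairs of arrays that stood far apart. OYE3 had 8.94 and 14.15 on the arrays labelled untreated replicates 1 and 2, and 14.07 and 8.96 on those labelled allyl alcohol replicates 1 and 2.

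**Figure D1:**
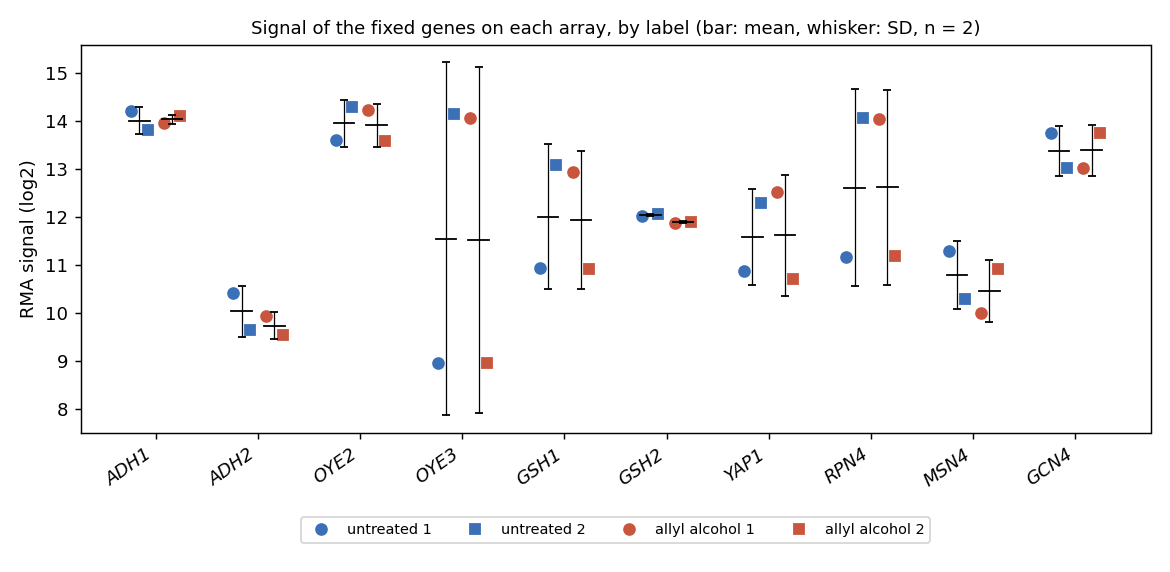
Log2 RMA signal of the 10 genes fixed beforehand on each array. Circles are replicate 1 and squares replicate 2, blue is untreated and red allyl alcohol, and bars and whiskers are the mean and SD (n = 2). For OYE3 the arrays labelled untreated replicate 2 and allyl alcohol replicate 1 lie at 14.15 and 14.07, and the other 2 at 8.94 and 8.96.

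Among genes whose groups did not overlap, the largest positive difference was that of FET3, the ferroxidase of high-affinity iron uptake, with a log2 difference of 0.91 (standard error 0.61) between 9.16 ± 1.01 and 10.07 ± 0.03 (SD, n = 2). It was 0.19 without the array labelled untreated replicate 1 and 1.62 without untreated replicate 2. PXR1 had 0.45, NOP2, an rRNA methyltransferase, had 0.43, RFU1 and NRG2 each had 0.42, NUG1 had 0.41, SPO19 had 0.39, ATF2, an alcohol acetyltransferase, had 0.38, FDH1, formate dehydrogenase, had 0.36, YSR3 had 0.35, and REA1 and IDP3, a peroxisomal isocitrate dehydrogenase, each had 0.34. The largest negative difference was that of ALD3, a cytosolic aldehyde dehydrogenase, with -0.56 (standard error 0.38) between 12.08 ± 0.13 and 11.53 ± 0.42, and it was -0.85 without allyl alcohol replicate 1 and -0.26 without allyl alcohol replicate 2. GCY1, an aldo-keto reductase, had -0.42 and ZTA1, a quinone reductase, had -0.36. The kinetochore genes NUF2 and DAD3 had -0.38 and -0.39. SPC24, another, had mean signals of 5.51 and 5.09 and was above background on 1 array, so no difference is given for it. YOR376W-A had -0.50, SWM2 -0.49, YPL216W -0.46, YNL146C-A -0.45, PCC1 -0.39 and NTA1 -0.39. The adjusted p in limma was 1 for all 24.

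Of the 5449 genes, limma called 0 at an adjusted p of 0.05, 0 had an unadjusted p under 0.05, and the smallest unadjusted p was 0.218. The groups did not overlap for 285 genes, or 5.23%, where chance gives 33.3%. The 1 gene with an absolute log2 difference of at least 1 was YMR001C-A, named after its values were seen, with -1.07 and overlapping groups. The median standard error of a log2 difference was 0.51 and the median half-width of its 95% interval was 1.47. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333.

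**Figure D2:**
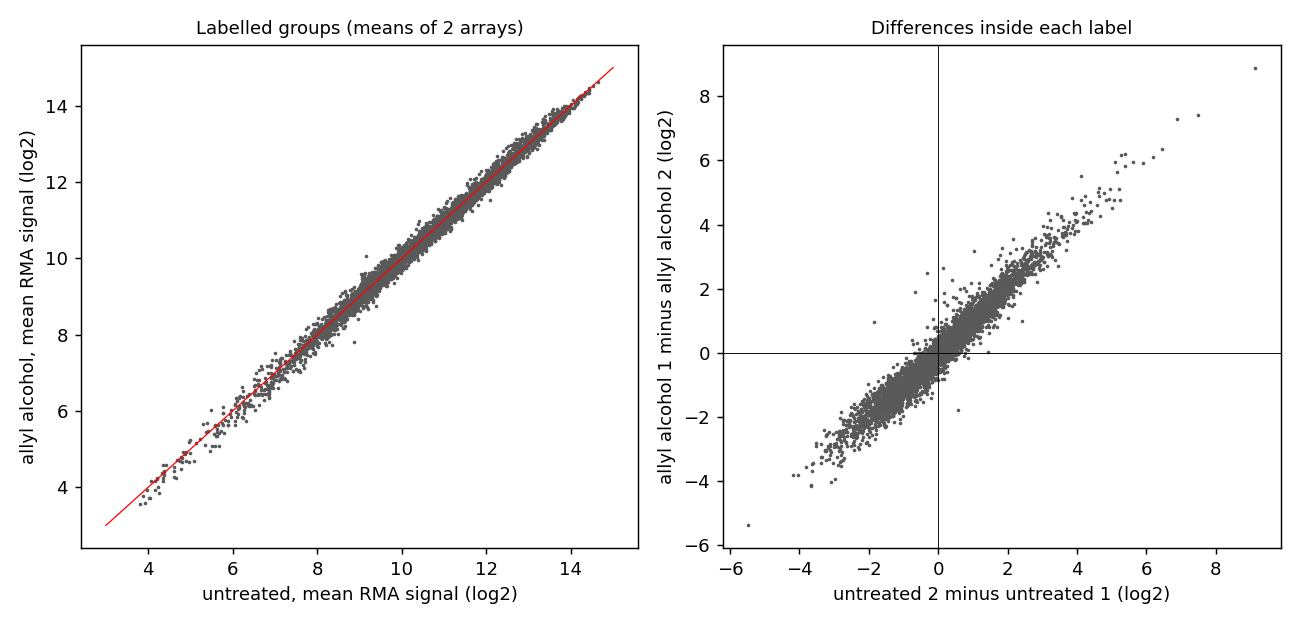
Left, mean log2 RMA signal of each of 5449 genes in untreated (x axis) and allyl alcohol (y axis) samples, with the line of equal values in red. Right, for the same genes, the log2 difference between the arrays labelled untreated (x axis, replicate 2 minus 1) and between those labelled allyl alcohol (y axis, replicate 1 minus 2). Differences between groups stay within 1.07 on the log2 scale, while differences inside a label reach 7.49 for YKL070W, above background on all 4 arrays. The outermost point is LSO1, below background on 2 arrays, so its place is not a measured difference.

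Of the 37 gene lists, 2 were shifted up and 2 down in camera with the preset correlation. Cytosolic ribosomal protein genes (127 measured) had a median log2 difference of 0.21 and ribosome biogenesis genes (81) one of 0.07, with adjusted p = 2.52e-13 and 1.22e-05. General stress genes (29) had -0.08 and trehalose and glycogen genes (17) had -0.11, both with adjusted p = 0.0404. All 4 calls were lost with an estimated correlation, where each list had adjusted p = 0.97, and in fry, where each had adjusted p = 0.997. No member of any list was called in limma, over all genes or adjusted over the list alone. Without the array labelled untreated replicate 2, the ribosomal protein median was -0.64 and that of ribosome biogenesis -0.29, and without allyl alcohol replicate 2 they were -0.39 and -0.49, against 1.10 and 0.40 without untreated replicate 1 and 0.85 and 0.64 without allyl alcohol replicate 1. The general stress call was lost without untreated replicate 1 or either allyl alcohol array, with medians of -0.21, -0.25 and -0.02 and adjusted p = 0.39, 0.653 and 0.458 in that order of arrays. The trehalose and glycogen call was lost without the same arrays, with medians of 0.08, -0.06 and -0.21 and adjusted p = 0.169, 0.722 and 0.141.

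The lists closest to acrolein chemistry did not pass the test. Median log2 differences were -0.07 for 22 Yap1 targets, -0.05 for 29 glutathione genes, -0.16 for 5 aryl-alcohol dehydrogenases and -0.06 for 6 aldehyde dehydrogenases, with adjusted p = 0.885, 0.657, 0.264 and 0.116 in camera with the preset correlation. For Yap1 targets each group joined a high and a low array. Their median log2 signal was 10.96 and 13.78 on untreated replicates 1 and 2. It was 13.67 and 10.89 on allyl alcohol replicates 1 and 2. The small median difference of this list therefore does not show that its genes were level across the arrays. The medians of all 37 lists lay between -0.19 and 0.21. Median, mean and test differed in sign for the sulfur assimilation list (median -0.01, mean 0.01, tested upward), the Gcn4-type amino acid synthesis list (median -0.00304, mean 0.02, upward), the DNA damage list (median -0.03, mean -0.05, upward) and the glycolysis list (median -0.01, mean -0.03, upward).

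Differences between arrays of the same label were far larger than those between the group means, in which a high and a low array cancel. They ran through named pathways. Between single arrays, 38.03% of genes were at least 2-fold apart inside untreated and 40.8% inside allyl alcohol. Same-numbered arrays of different labels were about as far apart, with 39.48% for replicate 1 and 39.68% for replicate 2. The differences inside a label compare single arrays and carry no test in this part. Their only repeat is the other label, where the differences in crossed order correlated at 0.973 across genes. The order of subtraction was chosen after the values were seen. In all, 1014 genes were at least 2-fold higher on the array labelled untreated replicate 2 than on untreated replicate 1 and also on allyl alcohol replicate 1 than on allyl alcohol replicate 2, and 862 were at least 2-fold lower in both. With the genes quantile normalized anew, these counts were 931 and 934. Among the 1876 genes at least 2-fold apart inside both labels, 0 had the same replicate higher in both.

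Genes of oxidant and electrophile defence stood higher on untreated replicate 2 and allyl alcohol replicate 1. The alcohol dehydrogenase list did not, with medians of -0.20 inside untreated and 0.21 inside allyl alcohol, 3 of 10 members higher and 2 lower. Nor did the aldehyde dehydrogenase list, with -0.14 and 0.003, 1 of 6 members higher and 1 lower. In the 22 measured Yap1 targets the median log2 difference was 1.63 inside untreated and 1.56 inside allyl alcohol, and 12 members were at least 2-fold higher and 0 lower in both. SRX1, sulfiredoxin, differed 88.3-fold and 81.8-fold, OYE3 36.9-fold and 34.6-fold, and FRM2 37.6-fold and 27.4-fold. Glutathione genes had medians of 0.81 and 0.75, with 12 of 29 higher and 1 lower. The peroxidase GPX2 differed 18.7-fold and 16.5-fold, and the transferase GTT2 18.4-fold and 16.6-fold. Thioredoxin, peroxiredoxin, catalase and superoxide dismutase genes had medians of 0.71 and 0.68. Of the Yap1 targets 13 were also in another list, as were 7 of the 29 glutathione genes and 8 of these 18. Such lists are therefore not separate results. The aryl-alcohol dehydrogenase list had 2.39 and 2.43, with AAD6 differing 59.8-fold and 60.3-fold, but this family is near-identical in sequence and its probe sets can share signal.

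Sulfur assimilation and methionine genes had medians of 1.91 inside untreated and 2.07 inside allyl alcohol in the same direction, with 18 of 30 members at least 2-fold higher and 1 lower in both. MET2, homoserine acetyltransferase, differed 118-fold and 158-fold, and the sulfate permease gene SUL1 24.2-fold and 32.1-fold. The proteasome and heat shock lists had the same direction, unlike the unfolded protein response list described below. Proteasome genes had medians of 1.01 and 0.92, with 15 of 33 higher and 0 lower, and RPN4 itself differed 7.46-fold and 7.33-fold. Heat shock genes had 0.84 and 0.92, with 10 of 25 higher and 0 lower, and HSP30 differed 27.4-fold and 31.6-fold. DNA damage-induced genes had 1.37 and 1.56, with the alkylation repair glycosylase MAG1 at 6.34-fold and 6.65-fold and RAD54 at 7.75-fold and 7.45-fold; over single unambiguous probe sets these medians were 1.10 and 1.12. The iron regulon had 1.63 and 1.12, with 15 of 24 higher and 0 lower. Lists of other functions also stood higher: gluconeogenesis (1.28 and 1.66), beta-oxidation (1.16 and 1.34), autophagy (1.12 and 1.08) and pleiotropic drug resistance (1.19 and 1.11).

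Cytosolic ribosomal protein, ribosome biogenesis, unfolded protein response, ergosterol, G2/M and mating type a lists stood lower on those arrays. Respiratory chain genes, with medians of -0.64 inside untreated and -0.77 inside allyl alcohol, and Gcn4-type amino acid synthesis genes, with -0.49 in both, were lower too. Cytosolic ribosomal protein genes had medians of -1.66 inside untreated and -1.25 inside allyl alcohol, with 77 of 127 members at least 2-fold lower and 0 higher in both, although paralogous pairs can share probes. Ribosome biogenesis genes had -0.78 and -1.09, with 30 of 81 lower and 2 higher. Unfolded protein response genes had -1.66 and -1.60, and ergosterol synthesis genes had -1.15 and -1.27, with 14 of 24 lower and 0 higher. Genes of the G2/M phase had -1.25 and -1.41, where the B-type cyclin CLB1 was higher by a log2 difference of 3.37 on untreated replicate 1 and 3.42 on allyl alcohol replicate 2. Other lists of related function did not stand as far apart: G1/S genes had -0.20 and -0.27, with 5 members higher and 4 lower, histone genes had -0.27 and -0.32, and mitochondrial ribosomal protein genes had 0.09 and 0.08. Mating type a genes had -2.12 and -2.07, including STE2, the alpha-factor receptor, and BAR1, the alpha-factor protease. The general stress list had 0.11 and 0.34, with members going both ways.

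In the same arrays the Bacillus poly-A control probe sets, which follow RNA added at labelling, had median differences of 0.88 inside untreated and 1.14 inside allyl alcohol in that direction, while the hybridisation controls had 0.20 and 0.14. The 3' minus 5' signal of ACT1, a measure of RNA integrity, lay between 0.18 and 0.27 on all arrays. The ribosomal RNA probe sets had median differences of -0.67 inside untreated and -0.27 inside allyl alcohol for 18S, and 0.11 and 0.69 for 25S. Of the 37 lists, 14 had medians above nearly all random lists in both labels, among them Yap1 targets at the 100th percentile in both, and 8 below nearly all, among them unfolded protein response genes at percentile 0 in both. Lists that share members were counted separately. Random lists lack the shared movement of a list's genes, so these percentiles are no p-values. For Yap1 targets that movement was estimated as a correlation of 0.91. The estimate rests on the same differences inside the labels, so it restates them and is no separate evidence. The differences inside the 2 labels correlated at 0.973 across genes, so the labels largely repeat each other. The 14 include the hexose transporters, whose medians of 1.23 and 1.39, with 8 members higher and 5 lower, became -0.09 and 0.11 when the genes were quantile normalized anew; percentiles were not recomputed under other scalings.

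**Figure D3:**
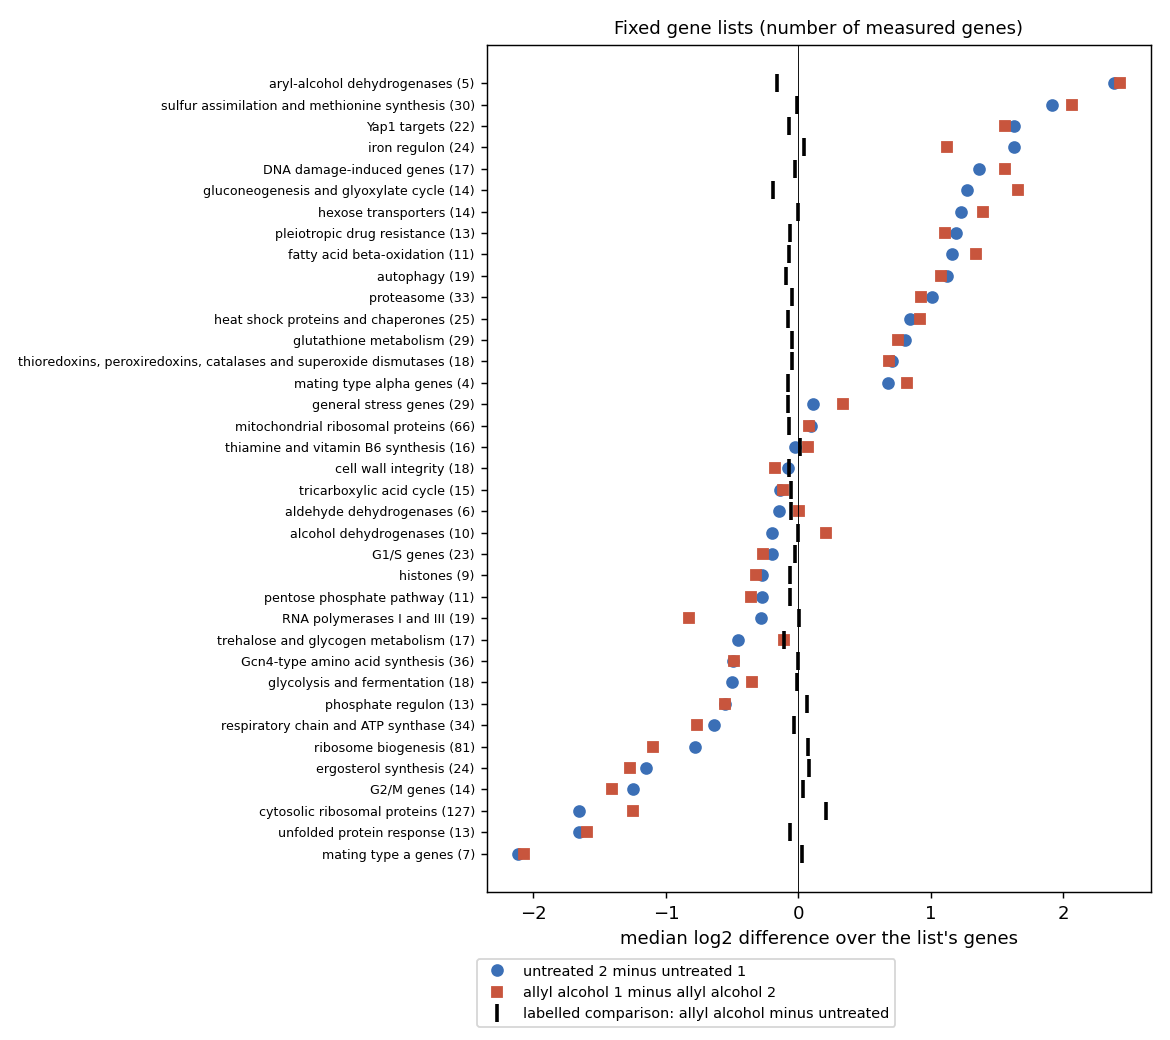
Median log2 difference over the measured genes of each fixed list, with the number of genes in brackets. Blue circles are the array labelled untreated replicate 2 minus replicate 1, red squares allyl alcohol replicate 1 minus replicate 2, and black ticks the labelled comparison. The ticks lie between -0.19 and 0.21, while the points reach 2.43 and -2.12.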

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

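The crossed block and the settings of the differences between arrays of the same label were chosen after seeing the data. The number of genes called by limma was 0 under every setting run, with 0 genes at an unadjusted p under 0.05, except 188 genes with the crossed block (smallest adjusted p 0.94) and 9 probe sets when all probe sets of the array were tested. The replicate numbers did not pair the arrays: the correlation across genes of same-numbered arrays' deviations from their group means was -0.973. With the replicate number as a block, limma called 0 genes and camera 3 lists up and 2 down, where the trehalose and glycogen list lost its call (adjusted p = 0.069), and the gluconeogenesis list gained one downward (adjusted p = 0.0106) and the iron regulon one upward (adjusted p = 0.0428). With the block that pairs the arrays crosswise, camera called 4 lists up and 4 down. With an estimated correlation and in fry, 0 lists were called up and 0 down. With members of a single list only, 0 lists were called down, though the medians were not smaller: -0.087 for general stress (adjusted p = 0.103) and -0.119 for trehalose and glycogen (adjusted p = 0.0543), over fewer genes. Apart from the settings named here and those without an array, the list counts stayed within 1.5 times. Calls were gained there too: mitochondrial ribosomal proteins downward with an intensity trend, without dim probe sets and after quantile normalization anew (adjusted p = 0.0493, 0.0385 and 0.0189), and the iron regulon upward without dim probe sets (adjusted p = 0.0355). With the values as deposited and an estimated correlation, both lists and the gluconeogenesis list had adjusted p = 0.97; it was not estimated under these settings or with the block. For 49 genes the mean signal over arrays was not above the mean background.

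Several small list medians changed sign with the scaling, none of them called: alcohol dehydrogenases 0.000134 after quantile normalization anew and 0.0144 after centring, sulfur assimilation 0.0177 and 0.00317, glycolysis 0.00612 and 0.00449, hexose transporters 0.0381 and 0.0158 and also 0.0235 without dim probe sets, and Gcn4-type amino acid synthesis 0.0017 and 0.013. Inside allyl alcohol, the aldehyde dehydrogenase median became -0.00943 and -0.0303 under the same scalings. Inside untreated, the hexose transporter median became -0.0863 after quantile normalization anew (0.115 inside allyl alcohol), and the thiamine and vitamin B6 median became 0.11 with single unambiguous probe sets. The cause was not tested.

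Leaving out an array leaves a group with 1 array, which is assumed to vary like the other group. Camera then called between 9 and 11 lists up and between 7 and 13 down. Lowest and highest log2 differences were -0.17 and 0.23 for ADH1, -0.67 and 0.0805 for ADH2, -0.39 and 0.30 for OYE2, -2.63 and 2.57 for OYE3, -1.15 and 1.00 for GSH1, -0.87 and 0.93 for YAP1, -1.44 and 1.45 for RPN4, -0.84 and 0.15 for MSN4, and -0.37 and 0.38 for GCN4. The genes named for their size of difference could not change sign, since they were chosen for groups that did not overlap. Their ranges were wide: 0.19 to 1.62 for FET3, 0.16 to 0.67 for NRG2, 0.10 to 0.60 for YSR3, -0.85 to -0.26 for ALD3 and -0.59 to -0.13 for ZTA1 are among them. Lowest and highest list medians were -0.88 and 0.75 for Yap1 targets, -1.38 and 1.05 for aryl-alcohol dehydrogenases, -0.51 and 0.30 for glutathione, -0.40 and 0.31 for thioredoxins and related enzymes, -1.04 and 0.99 for sulfur assimilation, -0.43 and 0.72 for pleiotropic drug resistance, -0.55 and 0.38 for heat shock, -0.53 and 0.49 for the proteasome, -0.39 and 0.0826 for trehalose and glycogen, -0.64 and 1.10 for cytosolic ribosomal proteins, -0.086 and 0.0164 for mitochondrial ribosomal proteins, -0.49 and 0.64 for ribosome biogenesis, -0.38 and 0.38 for RNA polymerases I and III, and -0.81 and 0.75 for DNA damage. They were -0.12 and 0.00277 for G1/S, -0.73 and 0.69 for G2/M, -0.18 and 0.20 for histones, -0.14 and 0.12 for the tricarboxylic acid cycle, -0.38 and 0.34 for the respiratory chain, -0.23 and 0.23 for glycolysis, -0.22 and 0.14 for the pentose phosphate pathway, -1.02 and 0.63 for gluconeogenesis, -0.72 and 0.60 for beta-oxidation, -0.80 and 0.44 for hexose transporters, -0.24 and 0.27 for Gcn4-type synthesis, and -0.71 and 0.58 for autophagy. They were -0.80 and 0.85 for the unfolded protein response, -0.54 and 0.70 for ergosterol, -0.78 and 0.85 for the iron regulon, -0.19 and 0.35 for the phosphate regulon, -0.00144 and 0.13 for thiamine and vitamin B6, -1.14 and 0.98 for mating type a genes, and -0.48 and 0.34 for mating type alpha genes. General stress and aldehyde dehydrogenase medians kept their sign, at -0.25 to -0.02 and -0.42 to -0.07. So did those of alcohol dehydrogenases, at -0.30 to -0.01, and cell wall integrity, at -0.19 to -0.03.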

Other observations

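All tests in this part were chosen after the arrays' values were seen. Outside the lists, the widest differences between arrays of the same label reached genes of several kinds, given as log2 signals in the order untreated replicates 1 and 2, then allyl alcohol replicates 1 and 2, and named after their values were seen. LSO1 had 3.45, 12.59, 12.48 and 3.59, below background on 2 arrays, so that its difference was at least 7.005 inside untreated and at least 6.85 inside allyl alcohol. YKL070W had 6.66, 14.15, 13.98 and 6.55, and REC104, a gene of meiotic recombination, had 7.43, 12.38, 12.50 and 7.40. In the other direction YOR387C had 13.23, 7.75, 8.10 and 13.47. The biotin synthesis gene BIO4 had 10.84, 6.65, 6.67 and 10.48. DSE4, a glucanase of cell separation, had 11.77, 8.55, 8.45 and 11.78, the ammonium permease MEP2 had 13.04, 9.89, 9.73 and 13.04, and the low-affinity iron transporter FET4 had 11.62, 8.02, 8.37 and 11.80.

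The 4 arrays formed 2 close pairs, each with 1 array of either label, and the first principal component, with 97.42% of the variance over genes, had scores of -46.79, 47.54, 49.08 and -49.83 in the same order. A smooth trend with brightness as the whole cause is argued against by 1743 of 1876 genes (92.91%). These stayed at least 2-fold apart inside both labels after a lowess trend on mean signal was removed. RMA had already quantile normalized the arrays, so this does not reach other effects of normalization or labelling. The poly-A controls, which follow RNA added at labelling, moved in the same direction by 0.88 and 1.14. What moved them was not tested. Culture batches crossed with the replicate numbers that share a large treatment effect over many genes are argued against by the labelled differences inside the 2 close pairs. These had a Pearson's r of -0.0621 and a Spearman's rho of -0.00371 across 5400 genes above background, genes not being independent. Their SDs were only 0.18 and 0.24, so a small effect or one in few genes is not excluded. An exchange of labels between 1 untreated and 1 allyl alcohol sample stays open, but the ratio of the larger SD of gene differences in a close pair to the smaller SD inside a label, 0.189, restates the pattern that prompted it and is no separate evidence for it. Batches crossed with the replicate numbers without any treatment effect cannot be told apart from such an exchange by the genes apart inside a close pair. Both leave few there (at most 0.275% at least 2-fold apart). The lists that stood apart between the close pairs, described above, were not used to weigh these explanations, because no prediction was written for them. An unrecorded difference between the cultures was not tested. Which arrays would carry a wrong label was not inferred, and no result above uses changed labels.

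The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The labelled split called 0 genes in limma and the highest of the other splits 4265. With a count of 0, all 3 of the 3 splits call at least as many whatever the data, so this comparison decides nothing. The split with 4265 genes follows the close pairs already described, so it repeats that structure of the samples and is no further evidence of its origin.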
